A study of Gallus gallus with 3 samples.

How the data were processed

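RNA of DT40 cells was measured on 3 one-colour arrays, 1 each for untreated cells, BP5 (0.02 µg/ml) and BSP-II (2 µg/ml), all at 4 h. Per the labels, Cy3-labelled cRNA was made from total RNA. The submitters' design text speaks of more than 1 experiment and of several cell populations, and how these relate to the 3 arrays is not given in the sources used here. Per the file headers, the arrays shared 1 slide, the control array was read in scan 1 and both peptide arrays in scan 2, and the spots were read with Agilent Feature Extraction 10.5.1.1 on a grid whose name gives the galGal3 assembly.

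The deposited intensity of each spot was background-subtracted and spatially detrended by Feature Extraction, with dim spots set to a floor, per the file headers, and was not normalized between arrays. Flags of 0 or 1 per spot mark spots well above background, saturated spots and outliers, per the file headers. The authors also deposited a table of log2 values of 20085 probes. Its columns correlated with log2 of the processed intensity of the same arrays at 1.000 each, with slopes of 0.978 to 1.03, and its medians were 7.75 in each of the 3 columns. The columns share a median and are not centred per gene; the normalization and the filter behind them are not given in the sources used here. This table served only as an alternative source of values.

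Each array held 43451 spots, of which 1417 were control spots and were left out, as were 153 probes with an outlier flag on any array. The 75th percentile of the processed signal was 254.8 on the control array, 178.7 on the BP5 array and 154.1 on the BSP-II array, the median local background 43.5, 54.0 and 54.5, and 0 probes were saturated. The lowest signal called well above background was 30.2, 49.1 and 36.7. Spots for spike-in transcripts (320 per array) were not well above background on any array, so they gave no check of amounts. Probes were named through their RefSeq accession, matched without version to the GRCg7b gene table, which was used for names only: 4000 of 5017 probes with such an accession matched, giving 3870 genes, 3759 with 1 probe and 111 with several. Gene names rest on these accessions, and the signals of probe pairs of 1 accession correlated at only 0.316 (280 pairs). The other 38034 probes stay unnamed here, and no coordinates are given because the assemblies differ.

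Log2 of the processed signal minus the array's 75th percentile over probes was the measure, as fixed before the data were examined. A gene's log2 ratio was the mean over its probes that were well above background and unsaturated on both arrays, and a gene counted as higher or lower at 2-fold or more with all such probes of 1 sign. Fewer than 50% of probes were detected on each array, so the percentile over probes well above background on all 3 arrays was run as an added alternative. With 1 array per group no test between groups was made. A gene well above background on 1 array only has a bound: its normalized value there minus its value on the other array, or minus the lowest value well above background on that array where this is higher. Named genes followed a rule fixed before the data were examined: the 8 largest increases and decreases per peptide among genes past 2-fold with signals above the array median on both arrays, the 3 largest bounds each way, 2 members per list with the largest ratios, the 6 largest shared changes each way, and the 5 largest each way between the peptides. All genes past 2-fold were above the array median, so the part of the rule for dimmer genes (the 3 largest each way) named 0, and 0 symbols were skipped as clone names. Some genes this rule picks are not reported here. Genes named only for being detected, and those listed with the areas of the array, were named after their values were seen.

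Gene lists, 27 in all, were fixed before the data were examined, for B cell, DNA repair, cell cycle, immune signalling, stress, metabolic, ribosomal and other cell type genes. Members were matched by the symbols written in each list. A first version also used the gene table's synonyms and was given up after its members were seen, because some belong to other genes, and is kept as an alternative. The median log2 ratio of a list with at least 5 measured members was ranked among 10000 random lists of the same size matched on signal in 20 bins. This describes these arrays and is not a test between conditions. The lists for p53 targets (4 measured), histones (3), T cell markers (2) and erythroid and thrombocyte markers (3) were too short. In the first of these 0 genes were past 2-fold in any comparison, with DDB2 at 0.50 for BP5. In histones 0 were past 2-fold, with H3F3B at 0.58 and 0.77 for BP5 and BSP-II, and the T cell markers CD247 and CD3D were not past 2-fold either. Unchanged arrays sharing a control were simulated 100 times by drawing each array's errors from the differences between both peptide arrays at like signal, with random signs.

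The steps were tested on simulated data for BP5 against control (2578 genes, 20 runs, 50 genes per fold), with errors drawn from the differences between both peptide arrays. Those arrays share a scan, and their gene ratios had a standard deviation of 0.349, against 0.548 for BP5 against control. With the control array, more unchanged genes may therefore pass and fewer changed genes and shifted lists may be found than given here. Of genes changed 1.5-fold 8.0% passed 2-fold, of genes changed 2-fold 49.3%, 3-fold 95.7% and 4-fold 99.3%, and 1.76% of unchanged genes passed, 42.0 per run. Of 200 unchanged lists of 14 genes, 4.5% lay outside the central 95%, and 90.5% of such lists shifted by 0.3 did. These lists were drawn at random from the same genes with independent errors, so the share of unchanged lists outside was built in. It does not cover lists whose members vary together, and neither do the 1.2 lists expected by chance in each comparison.

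The alternatives were quantile normalization, cyclic loess, the median of probes well above background on all 3 arrays, normexp background correction with offset 50, the authors' table, no filter on dim probes, a filter at the array median, the brightest probe per gene, saturated probes kept, subtraction of the median in a 10 by 10 grid of the array, fold thresholds of 3 and 1.5, and random lists not matched on signal. The files hold no mean spot signal, so normexp used the median spot and background signals. Subtraction of the median of the 15 nearest measured probes, leaving out disturbed areas (columns 1 and 2, and probes whose 15 nearest neighbours have a median more than 0.5 in log2 ratio from that of all probes), the percentile over probes well above background on all 3 arrays and matching through synonyms were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.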

Results

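DT40 cells, a chicken B cell lymphoma line, were left untreated (0 µg/ml) or exposed for 4 h to 1 of 2 peptides derived from the bursa of Fabricius, the organ in which birds form B cells. BP5 was given at 0.02 µg/ml and BSP-II at 2 µg/ml, and RNA was measured on 1-colour Agilent chicken arrays of 42034 probes. Each of the 3 groups was represented by 1 array (replicate 1 in the labels), so no difference reported here has a replicate check, and no p-value, standard error or standard deviation between replicates can be given. The number of arrays limits the precision. On the control array 19592 probes (46.6%) were well above background, on the BP5 array 15991 (38.0%) and on the BSP-II array 16656 (39.6%). A gene symbol could be given to 4000 probes, for 3870 genes, of which 2838 were detected on the control array, 2634 on the BP5 array and 2671 on the BSP-II array. The ± given with a log2 ratio is the scanner software's error of the spots on both arrays, which had a median of 0.20, and covers neither culture nor labelling.

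The first comparison asked which transcripts differ after 4 h of BP5. With BP5, MCM5, a subunit of the replicative helicase, was 16.2-fold lower than in the control (log2 ratio -4.02 ± 0.35), the largest decrease among the 2578 genes measured on both arrays. DNMT1, the maintenance DNA methyltransferase, was 6.47-fold lower (-2.69 ± 0.22) and CHAF1B, a subunit of chromatin assembly factor 1, was 5.80-fold lower (-2.54 ± 0.27). The largest increase among genes measured on both arrays was that of GDF3, a growth factor of the TGF-beta family, at 11.3-fold (3.49 ± 0.30). In all, 75 genes were at least 2-fold higher and 97 at least 2-fold lower, so 43.6% of the genes past 2-fold were higher. The balance turned under normexp background correction (41 higher and 34 lower, 54.7% higher, with 24 of the 75 and 34 of the 97 kept) and after the grid correction (77 and 67, 53.5%). It also turned with the scaling percentile (97 and 73, 57.1%) or median (85 and 84, 50.3%) taken over probes well above background on all 3 arrays. Without the filter on dim probes 760 were higher and 178 lower (81.0%). In that setting a probe at the floor of both arrays (6.06 on the control array, 9.85 on the BP5 array) comes out higher through floor and scaling alone. Those counts therefore say little about the balance. The median log2 ratio over all measured genes was -0.09.

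Among the other genes with large decreases with BP5 were SIKE1, a suppressor of the kinase IKK-epsilon (-3.03), MYLIP, a ubiquitin ligase of the LDL receptor (-2.89), STBD1, a glycogen-binding protein (-2.73), CASC4 (-2.60) and POP4, a subunit of RNase P (-2.58). SIKE1 lies in a disturbed area of the array and had a ratio of -3.70 after subtraction of the neighbouring probes. On the BP5 array MCM5 read 49.3 (1138 on the control array), STBD1 49.95 and MYLIP 55.6, close to the 49.1 of the dimmest probe called well above background there, while CASC4 read 219.5. The other large increases were those of the small GTPase RAP1B (3.01), ZNF302 (2.74), the acetylcholine receptor subunit CHRNA2 (2.46), the deubiquitinase YOD1 (2.41), the replication fork protein TIPIN (2.23), PGS1 (2.17) and PRLHR2 (1.89). All of these except CHRNA2 (column 3) and PRLHR2 (column 22) lay, like GDF3, in columns 1 and 2 at the edge of the array. Those at the edge stayed past 2-fold after subtraction of the neighbouring probes, from 1.65 for PGS1 to 2.79 for GDF3. Their neighbours lie partly in inner columns, so the subtraction can leave in place what columns 1 and 2 share. These columns held 24.0% of the genes higher with BP5 against 1.47% of all measured genes, and probes in column 1 had a median log2 ratio of 1.46. On the control array ZNF302 read 30.6, GDF3 40.5 and RAP1B 51.5, near the 30.2 of the dimmest probe called well above background there. The other large increases read 111.6 (CHRNA2) or more on that array. For genes detected on only 1 of the arrays the ratio is a bound: GPR89A was at least 5.81-fold higher with BP5 and OPCML at least 5.77-fold, both in columns 1 and 2. The splicing factor RBM10 was at least 6.36-fold lower, SKP1, a subunit of SCF ubiquitin ligases, at least 4.48-fold and KDSR, an enzyme of sphingolipid synthesis, at least 3.93-fold.

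Of all measured genes, 2.91% were at least 2-fold higher and 3.76% at least 2-fold lower with BP5. The lists of B cell and innate signalling are too short to be set apart from these shares. Of 17 measured genes of B cell identity and antigen receptor signalling, 13 lay above the median of all genes. LY86, the partner of the receptor CD180, was higher with BP5 (1.06 ± 0.21), 0 were lower, and the kinase BTK had a ratio of 0.70. Of 12 genes of Toll-like receptor and NF-kB signalling, the inhibitor NFKBIE was higher (1.46 ± 0.20) and the adaptor MYD88 lower (-1.20 ± 0.23). The interferon IFNW1 was the only cytokine past 2-fold of 6 measured (1.28 ± 0.26), and IRF1 the only one of 5 interferon-stimulated genes (-1.07 ± 0.34). IRF7, also on that list, was well above background on the control array but not on the BP5 array, so it is not among the 5. Of 12 immediate-early genes, the phosphatase DUSP6 was higher (1.09 ± 0.21) and MYC had a ratio of 0.56. PDCD4 was higher among 16 apoptosis genes (1.04 ± 0.20). CTNNB1, which encodes beta-catenin, was higher among 18 genes of MAPK, PI3K and Wnt signalling (1.02 ± 0.21), the glucose transporter SLC2A1 lower among 17 genes of glycolysis and hypoxia (-1.14 ± 0.20), and the mitotic kinase TTK lower among 26 mitosis genes (-1.15 ± 0.30). The small heat shock protein CRYAB was higher among 17 heat shock genes (1.23 ± 0.44), but its ratio was -0.08 after normexp background correction. After subtraction of the neighbouring probes MYD88 (-0.85), IRF1 (-0.75), SLC2A1 (-0.89), CTNNB1 (0.54) and CRYAB (0.84) were no longer past 2-fold, and of all genes 50 of the 75 higher and 48 of the 97 lower stayed so. MCM5, DNMT1 and CHAF1B were the only ones of 29 DNA replication genes past 2-fold.

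As groups, 2 of the 23 lists with at least 5 measured members had a median outside the central 95% of 10000 random lists matched on signal, where 1.2 are expected by chance. Ribosomal protein genes were shifted by 0.33 in log2 ratio (13 measured, 0 past 2-fold, 11 above the median of all genes, percentile 99.7), a shift that became -0.03 with quantile normalization and -0.01 in the authors' normalized values. RPLP1 had the largest ratio (0.50). Ribosome biogenesis genes were shifted by 0.28 (14 measured, percentile 98.7), although the members past 2-fold, NOL11 (-1.39) and TAF1B (-1.08), were lower; the list fell to percentile 86.0 after subtraction of the neighbouring probes, 89.6 after the grid correction and 95.9 against random lists not matched on signal. After the subtraction NOL11, which lies in a disturbed area of the array, and TAF1B had ratios of -0.19 and -0.93. The other lists lay inside. Percentiles were 95.1 for B cell genes (98.1, outside, against random lists not matched on signal), 93.7 for glycolysis and hypoxia, 89.6 for apoptosis, 73.9 for immediate-early genes, 54.0 for Toll-like receptor and NF-kB signalling, 55.5 for interferon-stimulated genes, 47.2 for MAPK, PI3K and Wnt signalling, 36.7 for heat shock, 33.9 for mitosis, 22.4 for cytokines and 5.82 for DNA replication. No member measured on both arrays was past 2-fold in homologous recombination (23 measured, percentile 76.4), cytokine receptors (11, 73.0), oxidative stress (18, 68.1), the unfolded protein response (20, 57.2), oxidative phosphorylation (9, 56.7), MHC and antigen presentation (8, 42.2), sterol synthesis (12, 26.3) or the proteasome (20, 23.2). Among markers of cells other than B cells, CLDN3 was higher (1.23) and the thrombocyte tubulin TUBB1 lower, though TUBB1 had a ratio of -0.56 after subtraction of the neighbouring probes. The 5 fibroblast, epithelial and endothelial markers lay at percentile 66.8 and the 6 macrophage and granulocyte markers at 7.12.

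The second comparison asked the same of BSP-II. MCM5 again had the largest decrease, 10.7-fold (-3.43 ± 0.26), among 2615 measured genes, and CHAF1B (-2.27 ± 0.24) and DNMT1 (-2.08 ± 0.21) were lower as well. GDF3 was 8.68-fold higher (3.12 ± 0.30). In all, 73 genes were at least 2-fold higher and 56 at least 2-fold lower (56.6% higher), with a median log2 ratio of 0.01. The counts were 46 and 52 without the disturbed areas, which turns the balance (46.9% higher), 64 and 19 under normexp (77.1%, with 29 of the 73 and 19 of the 56 kept) and 740 and 127 without the filter on dim probes (85.4%). As with BP5, the counts without the filter include probes at the floor of both arrays (7.36 on the BSP-II array), which come out higher after scaling. SIKE1 (-2.98, and -3.66 after subtraction of the neighbouring probes), CASC4 (-2.74), POP4 (-2.34), CCPG1, a receptor for autophagy of the endoplasmic reticulum (-2.15), and STBD1 (-2.06) completed the largest decreases. Among genes measured on both arrays, the largest increases after GDF3 were RAP1B (2.92), YOD1 (2.86), ZNF302 (2.81), TIPIN (2.79), ZMYND19 (2.60), LIMD2 (2.46) and PGS1 (2.39), all of them in columns 1 and 2 of the array. After subtraction of the neighbouring probes all stayed past 2-fold (from 1.67 for LIMD2 to 2.61 for YOD1). Probes in column 1 had a median log2 ratio of 1.58. The neighbours lie partly in inner columns, so the subtraction can leave in place what columns 1 and 2 share. These columns held 27.4% of the genes higher with BSP-II against 1.41% of measured genes. The ratios of GDF3, RAP1B and ZNF302 again rest on control readings near that of the dimmest probe called well above background. As bounds, GPR89A was at least 13.7-fold higher, MATN3, a cartilage matrix protein, at least 6.92-fold and OPCML at least 5.46-fold, again in columns 1 and 2. SKP1 was at least 5.17-fold lower, KDSR at least 4.53-fold and IRF7, a transcription factor of the interferon response, at least 4.19-fold.

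Immediate-early genes were shifted upward with BSP-II. Of 13 measured, 12 lay above the median of all genes (shift 0.33, percentile 99.3), and DUSP6 (1.00 ± 0.21) and RHOB (1.11 ± 0.40) passed 2-fold. RHOB lay in a disturbed area of the array and had a ratio of -0.06 after normexp, and the list lay inside the central 95% when position was corrected in a grid (percentile 87.1), after subtraction of the neighbouring probes (95.6), under quantile normalization (96.5) and in the authors' values (97.2). Genes of MHC and antigen presentation were shifted by 0.44 (8 measured, 0 past 2-fold, percentile 99.4), with RFXANK at 0.84 and the cathepsin CTSB at 0.60. That list lay inside after subtraction of the neighbouring probes (69.9), after the grid correction (85.8), under normexp (88.2), without the disturbed areas and with synonyms (93.6). Ribosomal protein genes were shifted by 0.34 (13 of 13 above the median of all genes, 0 past 2-fold, percentile 99.7), led by RPS15 (0.89) and RPLP1 (0.84). Random lists of like signal had a median of 0.26, against 0.01 for all genes, so they too lay above the median of all genes. As with BP5 the shift was -0.03 with quantile normalization and -0.01 in the authors' values. Mitosis genes were shifted by -0.17 (25 measured, percentile 1.93), with TTK lower (-1.53 ± 0.32) and CKAP2 at -0.74; the list lay inside under quantile normalization, cyclic loess (3.93), normexp, with synonyms and in the authors' values (7.06). These 4 of 23 lists lay outside the central 95%, against 1.2 expected by chance.

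In the remaining lists LY86 (1.08 ± 0.21) was higher among 16 B cell genes (percentile 69.3), NFKBIE (1.30 ± 0.20) among 12 genes of Toll-like receptor and NF-kB signalling (49.6), IFNW1 (1.11 ± 0.26) and IL4 (1.01 ± 0.44) among 7 cytokines (25.4), and CRYAB (1.69 ± 0.39) and HSPB1 (1.02 ± 0.26) among 17 heat shock genes (10.9). The 12 sterol synthesis genes lay at percentile 3.89 and the DNA replication list at 18.97. After subtraction of the neighbouring probes NFKBIE (0.94), IL4 (0.85) and RHOB (0.56) were no longer past 2-fold, DUSP6 lay just below it, and of all genes 52 of the 73 higher and 38 of the 56 lower stayed so. No member measured on both arrays passed 2-fold in glycolysis and hypoxia (17 measured, percentile 92.2), apoptosis (16, 90.1), ribosome biogenesis (14, 84.9), interferon-stimulated genes (5, 82.7), oxidative stress (18, 70.0), oxidative phosphorylation (9, 69.9), MAPK, PI3K and Wnt signalling (17, 44.6), cytokine receptors (10, 38.4), homologous recombination (23, 37.1), the proteasome (20, 26.7) or the unfolded protein response (20, 5.78), where XBP1 had the largest ratio (0.95). After subtraction of the neighbouring probes 3 of these lists lay outside the central 95%: homologous recombination (shift -0.25, percentile 0.210), interferon-stimulated genes (0.52, 97.7) and oxidative phosphorylation (0.20, 97.99). IRF7 belongs to the interferon-stimulated list but was not well above background on the BSP-II array, so it is not among the 5. By its bound it was at least 4.19-fold lower with BSP-II. It was not well above background on the BP5 array either, so its loss is not particular to BSP-II. The 6 macrophage and granulocyte markers lay at percentile 57.1 and the 5 fibroblast, epithelial and endothelial markers at 87.2, with 0 past 2-fold.

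**Figure D1:**
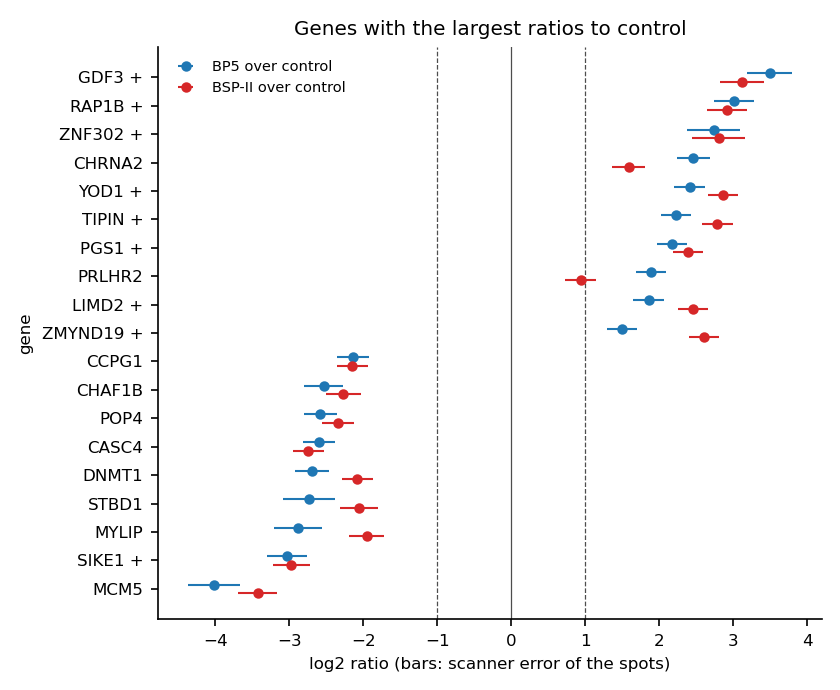
Log2 ratio of each peptide array to the control array (horizontal axis) for the genes with the largest ratios, with bars for the scanner's spot error and + for genes with a probe in a disturbed area or in columns 1 and 2. MCM5 lies farthest to the left with both peptides, at -4.02 with BP5 and -3.43 with BSP-II.

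Both peptides gave ratios to the control that moved together. Across the 2560 genes measured on all 3 arrays, 53 were at least 2-fold higher with both peptides and 38 at least 2-fold lower with both, and 0 passed 2-fold in opposite directions. The lower genes included MCM5, SIKE1, CASC4, POP4, CHAF1B, CCPG1 and TTK. Among the higher genes were GDF3, RAP1B, ZNF302, YOD1, TIPIN and PGS1 at the array edge, and LY86, NFKBIE, IFNW1 and DUSP6 elsewhere. Pearson's r across genes was 0.783, Spearman's rho 0.718 and the covariance 0.215, and 74.7% of genes had the same sign; genes are not independent replicates. In 100 simulated sets of unchanged arrays sharing 1 control, r averaged 0.498 (highest 0.548), rho 0.473, the covariance 0.0567 and the share of the same sign 66.2%. In the same sets 6.57 genes were higher and 7.16 lower with both (at most 14 each way), and independent lists of the observed sizes would share 2.00 and 2.01 genes. The covariance exceeded the simulated one by 0.159. The simulated sets give the control array the same errors as the peptide arrays, so they do not cover a noisier control array. The control array was read in scan 1 and both peptide arrays in scan 2, so scan and treatment cannot be told apart in either comparison with the control.

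**Figure D2:**
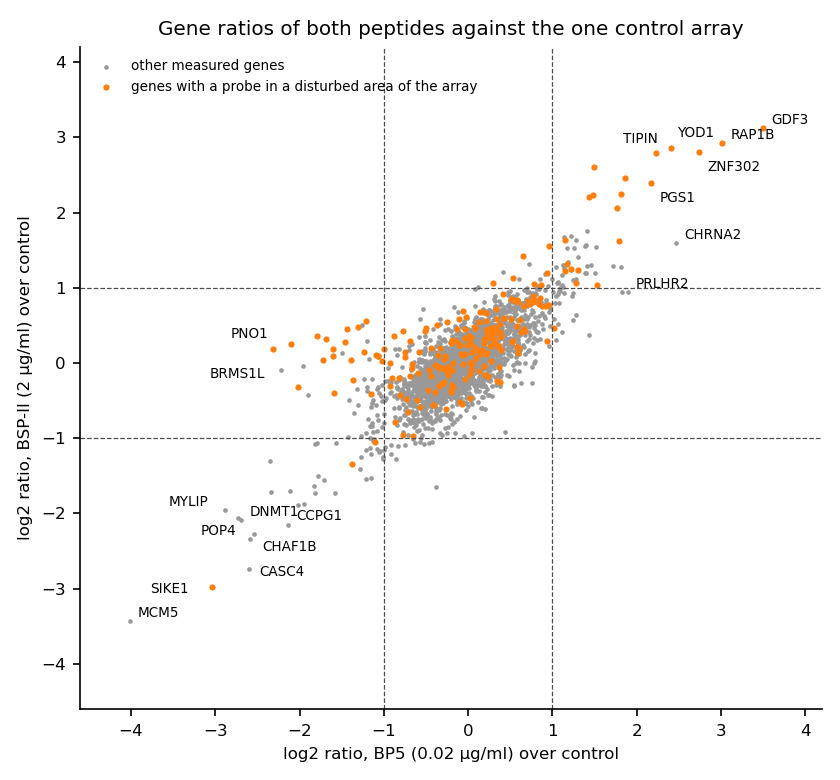
Log2 ratio to the control array with BP5 (horizontal axis) and with BSP-II (vertical axis), 1 point per gene measured on all 3 arrays, with dashed lines at 2-fold and in orange genes with a probe in a disturbed area or in columns 1 and 2. The cloud lies along the diagonal (r = 0.783).

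The peptides were also set against each other, at doses that differed, so that peptide and dose cannot be told apart. Both arrays came from scan 2. BASP1 was higher with BP5 than with BSP-II (1.26 ± 0.24), and so were SH2D6 (1.06 ± 0.24) and the splicing factor HNRNPH3 (1.03 ± 0.20), the only 3 of 2569 measured genes past 2-fold in this direction, in a comparison with a median log2 ratio of -0.11; with the percentile over probes well above background on all 3 arrays 8 were higher and 32 lower. Of 38 genes lower with BP5, the ribosome assembly factor PNO1 (-2.51), NAIF1 (-2.35), BRMS1L (-2.14) and TPD52 (-2.001) were among those with the largest ratios. Of these 38 genes 71.1% lay in disturbed areas of the array, against 3.15% of all measured genes. PNO1, NAIF1 and TPD52 lie in such an area (-1.53, -1.24 and -1.26 after subtraction of the neighbouring probes), and BRMS1L does not; the same subtraction left HNRNPH3 short of 2-fold (0.85). Without the disturbed areas 11 genes were lower.

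Immediate-early genes lay lower with BP5 than with BSP-II as a group (12 measured, shift -0.21, percentile 0.730), and were the only 1 of 23 lists outside the central 95%, against 1.2 expected by chance. The phosphatase DUSP1 was lower (-1.25 ± 0.21) and MAFF had a ratio of -0.67; the list lay inside at percentile 6.89 after subtraction of the neighbouring probes and 4.27 after the grid correction. MYD88 was lower (-1.49 ± 0.24) among 12 genes of Toll-like receptor and NF-kB signalling, a list just inside (percentile 2.55) that lay outside with the brightest probe per gene, after the grid correction and with synonyms (0.955); the probe of MYD88 lies in a disturbed area, and its ratio was -0.97 after subtraction of the neighbouring probes. NOL11 (-1.43, and -0.19 after the same subtraction), also in a disturbed area, was the only one of 14 ribosome biogenesis genes past 2-fold (percentile 87.8). The remaining lists had 0 genes past 2-fold. Their percentiles were 97.46 (just inside, and 97.89 without the filter on dim probes) for the unfolded protein response, 91.5 for homologous recombination, 87.8 for heat shock, 83.2 for mitosis, 80.5 for sterol synthesis, 79.3 for B cell genes, 72.2 for the proteasome, 62.9 for cytokine receptors, 59.96 for apoptosis, 54.0 for DNA replication, 53.3 for MAPK, PI3K and Wnt signalling, 51.0 for oxidative phosphorylation and 50.6 for glycolysis and hypoxia. On the lower side they were 38.7 for cytokines, 28.2 for fibroblast, epithelial and endothelial markers, 18.1 for oxidative stress, 13.1 for ribosomal proteins (0.480, outside, against random lists not matched on signal), 8.24 for MHC and antigen presentation (outside under quantile normalization, cyclic loess at 1.15 and in the authors' values), 7.95 for macrophage and granulocyte markers (2.38, outside, under normexp) and 7.61 for interferon-stimulated genes, which lay outside at 1.80 after subtraction of the neighbouring probes.

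**Figure D3:**
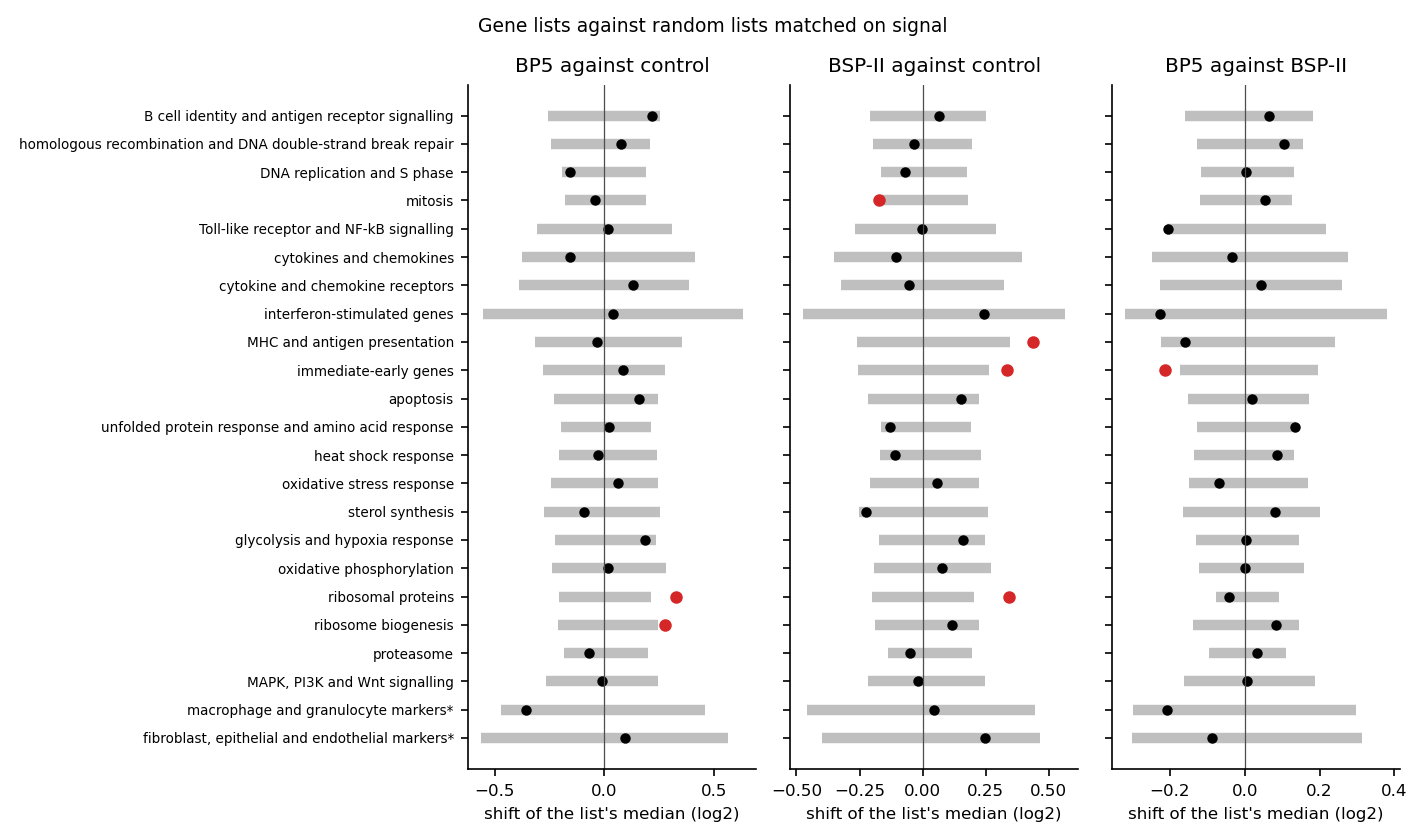
Shift of each list's median log2 ratio from that of random lists matched on signal (horizontal axis), with grey bars for the central 95% of 10000 random lists, red points for lists outside and an asterisk for other cell types. Ribosomal proteins lie to the right of the bar with both peptides, and immediate-early genes to the right with BSP-II and to the left in BP5 against BSP-II.

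Ratios depended on the position of a probe on the array. In both comparisons with the control, column 1 stood out (median log2 ratio 1.46 with BP5 and 1.58 with BSP-II), column 2 less (0.48 and 0.49), and the other columns had medians of -0.05 and 0.03. Of the 56 measured genes with several probes, 32 had probes of opposite sign for BP5 against control and 30 for BSP-II against control.

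**Figure D4:**
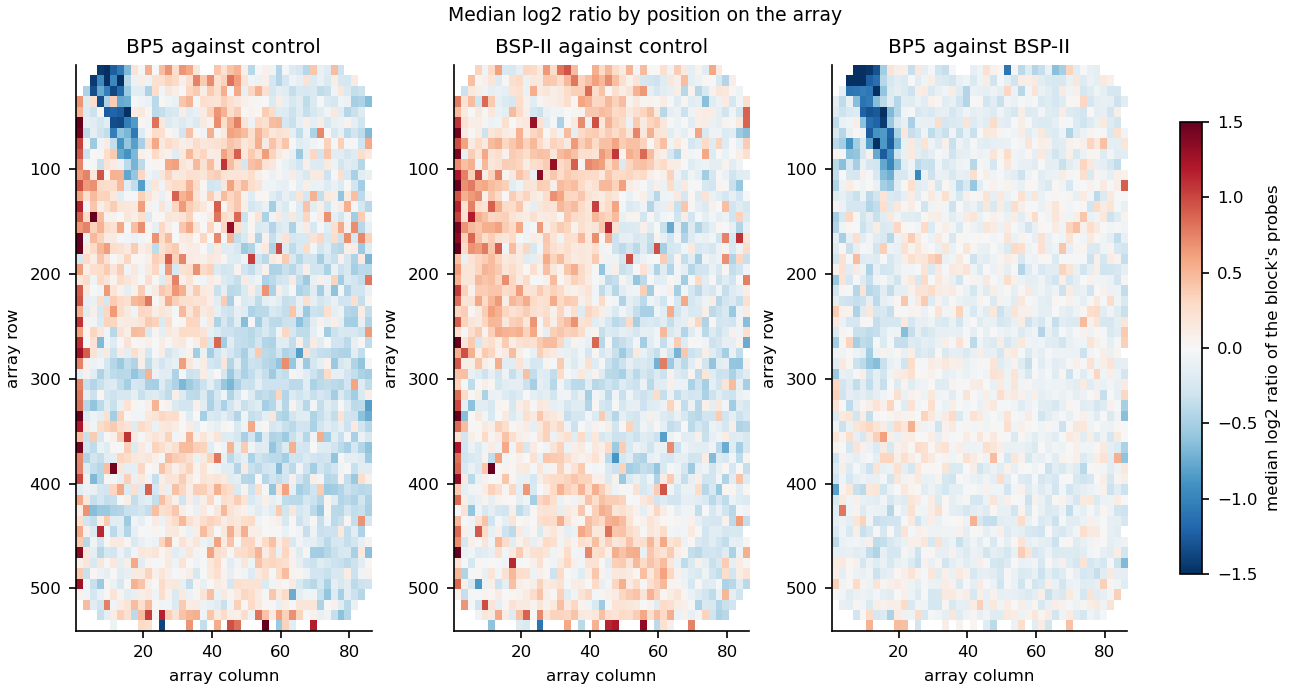
Median log2 ratio in blocks of 10 array rows (vertical axis) and 2 array columns (horizontal axis), for probes well above background on both arrays, red where the array named first is higher and blue where it is lower. Columns 1 and 2 are mostly red in both comparisons with the control, and the blue stripe at the upper left appears in both comparisons with the BP5 array.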

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

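All tests of explanations in this part were chosen after the result was seen.

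Probes without a gene symbol enter the scaling, the subtraction of neighbours and the map of the array, but no gene or list result above reports on them. Of 12699 such probes measured on all 3 arrays, 596 were at least 2-fold higher with both peptides (4.69%) and 179 at least 2-fold lower (1.41%). Among the 2620 probes with a symbol 54 were higher (2.06%) and 42 lower (1.60%).

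The first pattern weighed is that the ratios of both peptides to the control move together across genes (r = 0.783). Uneven signal that neighbouring probes share is argued against as the whole cause. Its subtraction changed 81 of 195 values of named genes beyond their error and left r at 0.760. A trend with brightness is argued against in the same way, with r at 0.789 after cyclic loess. The control array alone stays open: the part of the variance both comparisons share was 0.215, against 0.0841 for the BP5 array alone and 0.0373 for the BSP-II array alone, and the control's scan held 1 array. A response common to both peptides and a property of this single array, of its RNA or of its scan cannot be told apart.

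The second pattern is the set of 221 probes at least 2-fold lower with both peptides, MCM5, DNMT1 and CHAF1B among them. A loss of S phase cells large enough to lower the DNA replication genes 2-fold as a set is argued against for MCM5, DNMT1 and CHAF1B. The 29 DNA replication genes had a median log2 ratio of -0.17 (95% interval -0.37 to 0.04) over both peptides. A smaller loss of S phase cells is not excluded, with the list at percentile 5.82 for BP5 and 18.97 for BSP-II. A change of the whole transcript stays open for the 12 lower probes that have a second probe of the same accession: the second probes had a median of 0.0254 after subtraction of the neighbouring probes, against -1.75 for the lower ones, but over all 280 such pairs the ratios correlated at 0.054 (interval -0.08 to 0.19), so a second probe shows little about the first. The same was seen for 6 probes higher with both peptides (median 1.27), whose second probes had a median of -0.40. In both sets 0 of the second probes were past 2-fold in the same direction with both peptides. After subtraction of the neighbouring probes, pairs of like signal correlated at 0.260 in ratio (89 pairs, interval 0.01 to 0.47), against 0.0695 over all pairs. In signal all pairs correlated at 0.316, so the accessions that name the probes, that of MCM5 included, may be wrong in part. For MCM5, DNMT1 and CHAF1B the 3 probes are the only ones, so a fault of a single probe and a change of these genes cannot be told apart, and a response to the peptides stays untested.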

How the results depend on the processing

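The settings chosen after the data were seen were the 75th percentile over probes well above background on all 3 arrays (here detected probes), the subtraction of neighbouring probes, leaving out disturbed areas and matching through synonyms. No paired analysis was possible because each group holds 1 array, and leaving out a replicate could not be run for the same reason. Keeping saturated probes and filtering at the array median moved nothing (0 probes were saturated, and every gene past the filter for background was above the median), so they check nothing. The same holds for list shifts and the correlation under the median and the percentile of detected probes, which move every gene alike. Signal over background limits what could be measured: 22045 probes were not well above background on any array. Under the other settings, 75 counts and correlations were classed as little changed and 38 as moved. Of the list shifts 712 were classed as little changed, 43 as moved and 4 as reversed. Little changed does not mean that the sign was kept. The shift of interferon-stimulated genes for BP5, 0.04, fell as low as -0.25, and that of B cell genes for BSP-II, 0.06, as low as -0.05. Of 195 ratios of named genes 119 moved beyond their error under normexp, 81 after subtraction of neighbours, 68 after the grid correction, 24 in the authors' values, 23 under quantile normalization and 17 under cyclic loess; the other settings leave such ratios little or no room to move. Normexp kept 24 of the 75 genes higher and 34 of the 97 lower with BP5, and 29 of 73 and 19 of 56 with BSP-II. Except where stated, the cause was not tested.

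On the control array 33.7% of probes had the lowest signal of that array, on the BP5 array 43.4% and on the BSP-II array 41.3%. Without the filter on dim probes, a probe at this floor on both arrays comes out higher with each peptide after scaling. The counts against control, the shared counts and the correlation without the filter are therefore set in part by the floor. Counts past 2-fold are given as higher and lower. For BP5 against control they were 75 and 97 (43.6% higher), and became 41 and 34 under normexp (54.7%), 760 and 178 without the filter on dim probes (81.0%), 15 and 32 at 3-fold (31.9%) and 214 and 279 at 1.5-fold. For BSP-II against control 73 and 56 (56.6%) became 64 and 19 under normexp (77.1%), 740 and 127 without the filter (85.4%), 20 and 19 at 3-fold, 259 and 179 at 1.5-fold, and 46 and 52 without disturbed areas (46.9%). For BP5 against BSP-II 3 and 38 (7.32%) became 50 and 92 without the filter (35.2%), 0 and 16 at 3-fold, 55 and 148 at 1.5-fold (27.1%), and 8 and 32 with the percentile over detected probes. In that comparison 5 were higher with the median of detected probes and 1 under normexp, and 21 were lower after the grid correction, 15 after subtraction of neighbours and 11 without disturbed areas (21.4% higher). The share of higher genes for BP5 was 57.1% with the percentile over detected probes. Genes past 2-fold with both peptides, 91 in all, numbered 48 under normexp, 769 without the filter, 26 at 3-fold and 245 at 1.5-fold. The correlation, 0.783, was 0.757 under normexp, 0.852 without the filter and 0.760 after subtraction of neighbours.

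The median of all genes moved by over 0.1 under normexp (to 0.11 for BP5 and 0.17 for BSP-II), with the percentile over detected probes (to 0.04 for BP5 and 0.01 for BP5 against BSP-II), without the filter on dim probes (to 0.06 for BP5 and 0.14 for BSP-II), under cyclic loess for BP5 (to 0.02), and for BP5 against BSP-II under quantile normalization (0.02), cyclic loess (0.02) and the authors' values (0.03). List shifts are relative to random lists, matched on signal in all but 1 alternative, whose median can differ from that of all genes. The lists outside the central 95%, 7 over all comparisons, numbered 4 under quantile normalization, in the authors' values and after the grid correction.

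The shift of ribosomal proteins reversed under quantile normalization (-0.0256 for BP5 and -0.0316 for BSP-II) and in the authors' values (-0.0077 and -0.0082). CRYAB for BP5 (-0.0843) and RHOB for BSP-II (-0.0644) reversed under normexp. Other shifts moved under normexp for DNA replication (BP5 -0.0572, BSP-II 0.055), cytokine receptors (BP5 -0.12) and MHC (BSP-II 0.16). Without the filter on dim probes they moved for B cell genes (BP5 0.0818), Toll-like receptor and NF-kB signalling (BSP-II 0.15, BP5 against BSP-II -0.0289), cytokines (0.11 for each peptide), MAPK, PI3K and Wnt signalling (BP5 -0.21) and fibroblast, epithelial and endothelial markers (BP5 0.37). The grid correction moved, for BP5, DNA replication (-0.0451), sterol synthesis (0.0673), glycolysis and hypoxia (0.0317) and ribosome biogenesis (0.11), and for BSP-II Toll-like receptor and NF-kB signalling (0.15), cytokines (0.0911), MHC (0.11), immediate-early genes (0.11) and ribosome biogenesis (-0.0308). Subtraction of neighbours moved, for BSP-II, homologous recombination (-0.25, then at percentile 0.21), Toll-like receptor and NF-kB signalling (0.16), interferon-stimulated genes (0.52), MHC (0.0631), immediate-early genes (0.19), glycolysis and hypoxia (0.007), oxidative phosphorylation (0.20), ribosomal proteins (0.18) and ribosome biogenesis (-0.0031). It also moved ribosome biogenesis for BP5 (0.10) and, for BP5 against BSP-II, homologous recombination (0.0292), mitosis (-0.0158) and oxidative stress (0.0639). Without disturbed areas MHC moved for BSP-II (0.24). Against random lists not matched on signal, ribosomal proteins (BSP-II 0.59, BP5 against BSP-II -0.23), oxidative phosphorylation (0.21 and -0.14), the proteasome (0.0453 and -0.092) and heat shock (BP5 against BSP-II 0.0085) moved. With synonyms MHC (BSP-II 0.27) and the unfolded protein response (BP5 against BSP-II 0.0415) moved.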

Other observations

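The tests of explanations in this part were chosen after the result was seen.

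All 29 named genes of DNA replication and 16 of 27 genes of B cell identity and antigen receptor signalling were well above background on all 3 arrays, as were MYC, IRF4, XBP1 and JCHAIN. So were some markers of other cell types: 2 of 10 T cell markers (CD3D, a T cell receptor component, and CD247), 6 of 16 macrophage and granulocyte markers, AVD (the egg-white protein avidin) among them, 3 of 7 erythroid and thrombocyte markers and 5 of 23 fibroblast, epithelial and endothelial markers, THY1 and CLDN3 among them. Of 27 cytokines and chemokines 6 were detected on all 3 arrays, including LITAF, TGFB3 and IFNW1.

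Another pattern is that genes past 2-fold gather in areas of an array. An uneven area on the BP5 array is a candidate cause for the genes lower than with BSP-II that lie in disturbed areas: in the low areas outside columns 1 and 2, 157 unnamed probes had log2 ratios to control that differed from those of other probes by a median of -0.82 for BP5 (95% interval -0.95 to -0.72) and 0.15 for BSP-II. The 11 such genes outside disturbed areas had a median of -1.20 before and -1.04 after subtraction of the neighbouring probes, but the limit that defines the areas leaves that subtraction too little room to end the difference, so the cause stays open for ADCY9, BRMS1L, CNOT8, DUSP1, EIF4G2, MIB2, MPPE1, PARK7, PDCD10, RASD1 and RBMS1. For genes higher than control, dim outermost columns on the control array stay open as well: the 75th percentile of log2 signal in columns 1 and 2 minus the median of the other columns was -2.11 on the control array, but also -0.877 on the BP5 array and -0.834 on the BSP-II array. No other biological explanation was tested for this pattern.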
